A study of Mus musculus with 8 samples.

How the data were processed

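RNA-seq was carried out on 8 libraries of mouse spermatogenic cells at postnatal day 12, 4 Brg1 WT and 4 Brg1 cKO, and sample groups and replicate numbers were taken from the sample titles. Testes were digested with collagenase and trypsin, the cells were filtered and frozen, and libraries were made with a stranded mRNA kit, per the labels' protocols. The values used were estimated counts per gene symbol deposited by the authors, not scaled for depth or length. Reads were quantified with kallisto 0.42.5, and the build mm9 and edgeR are also named, per the submitters' processing notes. The annotation used and the way transcripts were summed to gene symbols are not given in the sources used here.

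The table held 28460 genes, of which 5463 had no count in any library. Because 49.6% of the values were not whole, the estimated counts were rounded to whole numbers before every count test. Totals per library ran from 20456700 to 32596000 estimated counts, and their number limits the precision of low genes. Mitochondrially encoded transcripts took 6.47% to 9.57% of a library and Trim2 2.56% to 5.96%. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 21.8, so none was treated as a library deposited more than once. This check says nothing of whether libraries came from separate animals, for which the design text was followed.

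Genes were filtered with filterByExpr by genotype, leaving 16059, normalized with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, genotype the only term, R 4.3.3). P-values were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM on TMM-scaled library totals as means ± SD over the 4 libraries, and list levels per library are means of log2 CPM with a prior count of 2.

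The 20 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Genes named were Smarca4, the 7 largest rises and the 7 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the libraries of the genotypes, leaving out provisional Gm and Rik symbols, and up to 3 called members of each list with the smallest adjusted p, or the most abundant member where none was called. A few genes that met this rule are not reported here, and no other gene took their place. Of 439 tested list members 9 stood in more than 1 list. Lists were tested against other genes with camera of limma 3.58.1 at an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists. Fry was used to test whether the members of a list changed, in a shared direction or in either, without a comparison with other genes. None of the 11 lists that camera called held with an estimated correlation. Among them, the DNA damage, pachytene and spermatid, and stromal lists did not pass fry's test of a shared direction (adjusted p = 0.084, 0.070 and 0.306). A further 9 lists were written later, 6 before and 3 after their values were seen, and adjusted over those 9.

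On simulated counts with 200 changed genes drawn from these libraries' means and sizes, over 16059 genes, the test recovered 54% and 34% of genes made 1.5-fold higher and lower and 70% and 68% of those made 2-fold higher and lower, and 8 of its 130 calls (6.15%) were unchanged genes. The calls included 9 of a further 25 genes lowered 1.4-fold to test camera. Far fewer genes were changed in the simulation than the 3312 called in the real data, which makes the adjusted threshold stricter. The recovered shares therefore do not carry over to the real fit. Alternatives tried were DESeq2 1.42.0, limma-voom, the edgeR exact test, RLE and upper-quartile factors, no filter, a filter of at least 1 CPM in at least 4 libraries, leaving out each library, the replicate number as a block and a test for changes over 1.5-fold. Chosen after seeing the data were the fits without Brg1 WT replicates 1 and 2, without mitochondrial transcripts, Trim2 and Tor1aip1, with GC content and length offsets, and with the median of the pan-germ cell, undifferentiated spermatogonia or Sertoli cell list taken as no change. Differences between lists were tested with exact two-sided permutation tests over the 70 assignments of genotype to libraries, for which 0.0286 is the smallest p. Gene names, GC content, length and chromosome membership came from a mouse annotation of a later build matched by symbol, so no coordinates are given.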

Results

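Gene expression was measured by RNA-seq in spermatogenic cells from the testes of mice at postnatal day 12, an age at which the first wave of germ cells has entered meiotic prophase. The 8 libraries came from 4 Brg1 wild-type samples (Brg1 WT) and 4 samples with a conditional knockout of Brg1 (Brg1 cKO), described in the series' design text as biological replicates. Brg1, encoded by Smarca4, is a catalytic ATPase of the SWI/SNF chromatin remodelling complex. The cells were obtained by enzymatic digestion and passage through a sieve, with no sort by a marker named in the labels, so that markers of the somatic cells of the testis were measured alongside germ cell genes. Library totals ran from 20456700 estimated counts in Brg1 cKO replicate 4 to 32596000 in Brg1 WT replicate 3. Levels are given as CPM, counts scaled to a common library total. Pearson correlations of log2 CPM across genes were 0.973 to 0.983 within Brg1 WT, 0.970 to 0.976 within Brg1 cKO and 0.950 to 0.975 between genotypes.

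Smarca4 was lower in all 4 Brg1 cKO libraries than in any Brg1 WT library. Brg1 WT replicates 1 to 4 had 347.5, 356.6, 346.9 and 337.9 CPM, and Brg1 cKO replicates 1 to 4 had 129.2, 122.3, 110.9 and 121.7 CPM. The means were 347 ± 7.68 and 121 ± 7.55 CPM (SD, n = 4 each), a log2 fold change of -1.52 ± 0.061 (SE, adjusted p = 6.8e-06, edgeR quasi-likelihood test). The part of the gene that was deleted is not given in the sources used here. Reads from the remaining exons, and from any cells without the deletion, count toward Smarca4.

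**Figure D1:**
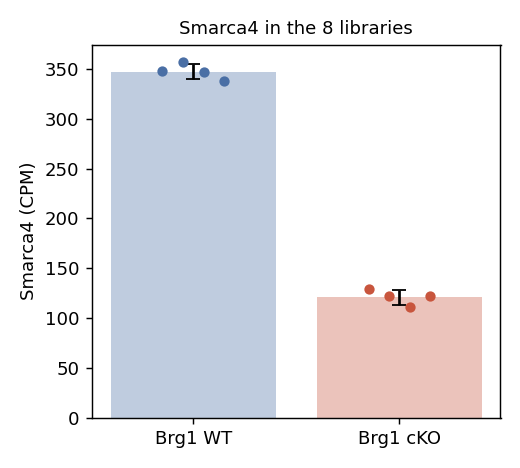
Smarca4 level in CPM (vertical axis) for each of the 8 libraries (points), with the mean (bars) and SD (error bars) of the 4 Brg1 WT and the 4 Brg1 cKO libraries. Brg1 WT libraries sit between 337.9 and 356.6 CPM and Brg1 cKO libraries between 110.9 and 129.2 CPM.

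The comparison of the genotypes asked which transcripts differ in Brg1 cKO in these cells of the P12 testis, somatic cells included. Whether a change lay in germ cells or in somatic cells was not tested. Loss of Brg1 was accompanied by steep falls of a few developmental transcription factors and by smaller rises. Tbx1, a T-box transcription factor, fell from 18.2 ± 2.22 to 2.35 ± 0.63 CPM (SD, n = 4 each), a log2 fold change of -2.95 ± 0.20 (SE, adjusted p = 1.8e-04). Foxf1, a forkhead factor of mesenchyme, fell from 24.8 ± 3.18 to 3.78 ± 0.92 CPM, and Dgkk, a diacylglycerol kinase, fell from 11.6 ± 2.14 to 1.84 ± 0.23 CPM. Foxn4 and Plk5 were 5.71-fold and 5.24-fold lower. Gml had 9.64 ± 6.34 CPM in Brg1 WT and 1.19 ± 0.34 CPM in Brg1 cKO (adjusted p = 0.0063). Mroh4 had 220, 176, 31 and 12 estimated counts in Brg1 WT replicates 1 to 4 and 3, 1, 1 and 0 in Brg1 cKO replicates 1 to 4, too few in Brg1 cKO for a fold to be given. Among the rises, Nefm, a neurofilament subunit, went from 5.79 ± 0.95 to 29.9 ± 14.9 CPM, a log2 fold change of 2.37 ± 0.32 (SE, adjusted p = 0.0034). Lpl, which encodes lipoprotein lipase, was 2.79-fold higher and Pdgfrl 3.26-fold higher in Brg1 cKO. Clec3b rose from 3.92 ± 0.42 to 13.1 ± 10.1 CPM, with 27.4 CPM in Brg1 cKO replicate 2 alone. Cldn1, a tight junction claudin, was 2.61-fold higher (adjusted p = 0.048). C1rb and Dsg1b were 3.61-fold and 2.80-fold higher, with the caution that each has close paralogs between which reads can be split. Among the Brg1 cKO libraries, C1rb, Clec3b, Pdgfrl, Lpl and Cldn1 were lowest in replicate 4, where stromal genes were lowest too. Nefm and Dsg1b were not lowest there.

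Across the 16059 genes tested, 3312 (20.6%) differed between the genotypes at an adjusted p under 0.05, with 1412 higher and 1900 lower in Brg1 cKO. DESeq2 called 4445, 2238 higher and 2207 lower. The balance moved with the level taken as no change, in fits chosen after seeing the data: 6101 genes were higher and 828 lower relative to the pan-germ cell median, 10643 and 407 relative to the undifferentiated spermatogonia median, and 72 and 8497 relative to the Sertoli cell median. Changes were mostly small: 65 of the higher and 424 of the lower genes changed at least 2-fold, and 6 and 62 at least 4-fold. The 4 libraries of each genotype did not overlap for 3007 of the called genes and for 4182 of all tested genes, where chance gives 2.86% of genes. Brg1 WT replicates 1 and 2 had higher levels of pachytene and spermatid transcripts than the other libraries, and without them 438 genes were called, 96 higher and 342 lower. Such a fall is not particular to that pair, since 244 genes were called without Brg1 WT replicates 1 and 3 and 270 without 2 and 3. Without replicates 3 and 4 the number was 2167. Counts of list members called without Brg1 WT replicates 1 and 2, given below, share this limit. The count also fell to 1608 without Brg1 cKO replicate 1, 1777 without Brg1 WT replicate 2, 1881 without Brg1 cKO replicate 3, 2037 without Brg1 WT replicate 1 and 2135 without Brg1 WT replicate 3.

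Of 30 tested genes of undifferentiated spermatogonia, the stem and progenitor population, 12 fell in Brg1 cKO, 3 rose and 15 were not called, with 13 lower and 3 higher when adjusted over the list alone. Upp1 fell from 9.96 ± 1.03 to 2.35 ± 0.31 CPM (SD, n = 4 each; log2 fold change -2.08 ± 0.15 SE, adjusted p = 2.0e-04) and Nanos3, an RNA-binding regulator of germ cell survival, from 3.96 ± 0.66 to 1.14 ± 0.28 CPM. Itga6, an integrin also made by other cell types, rose from 183 ± 5.34 to 248 ± 2.80 CPM. By edgeR, Nanos2 (log2 fold change 0.94, adjusted p = 0.040) and Bcl6b (0.63, adjusted p = 0.045) also rose. Nanos2 and Bcl6b were chosen after their values were seen. The list median was a log2 fold change of -0.50 and camera gave an adjusted p = 8.9e-04 for the list against other genes. With an estimated correlation this list had an adjusted p = 0.464. Without Brg1 WT replicates 1 and 2, 3 members were called lower and 1 higher, at a list median of -0.41. In the full set of libraries the Sertoli cell list had a median of 0.38, with 13 of 28 members higher, and a list of 20 pan-germ cell genes, written after values had been seen, one of -0.24.

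Differentiating spermatogonia genes showed 7 lower, 2 higher and 8 uncalled members of 17, with 11 lower and 2 higher when adjusted over the list alone. Esx1, an X-linked homeobox gene, was 2.19-fold lower, Prss50 2.36-fold lower, and Mki67, which marks cycling cells, fell from 396 ± 29.8 to 249 ± 21.1 CPM (log2 fold change -0.67 ± 0.081 SE, adjusted p = 0.0021). The list median was -0.38 (camera adjusted p = 0.0020, and adjusted p = 0.418 with an estimated correlation). In the same libraries the median of the Sertoli cell list lay 1.30-fold higher in Brg1 cKO. Calls without Brg1 WT replicates 1 and 2 were 5 lower and none higher, with 8 lower and 3 higher at an unadjusted p under 0.05.

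Of 21 tested genes of meiotic entry, cohesin and the synaptonemal complex, 14 fell, none rose and 7 were not called, with 17 lower when adjusted over the list alone. Gm1564, now named Meioc and required for the extended meiotic prophase, fell from 171 ± 25.3 to 73.4 ± 13.2 CPM (SD, n = 4 each; log2 fold change -1.22 ± 0.14 SE, adjusted p = 0.0021). Ccdc79, now Terb1, which tethers telomeres to the nuclear envelope, was 2.04-fold lower, and the meiotic cohesin gene Smc1b fell from 290 ± 23.4 to 197 ± 21.5 CPM. The meiotic recombination list had 17 lower, no higher and 12 uncalled members of 29, with 21 lower when adjusted over the list alone. Ccdc36, now Iho1, which takes part in DNA break formation, was 1.75-fold lower, Gm960 2.17-fold lower, and the crossover gene Msh5 fell from 27.6 ± 5.64 to 15.1 ± 1.24 CPM.

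Medians of these meiotic lists were -0.56 and -0.54, with camera adjusted p = 1.8e-08 and 4.5e-09. Each had an adjusted p = 0.418 with an estimated correlation. Without Brg1 WT replicates 1 and 2 the medians were -0.41 and -0.37 (camera adjusted p = 7.1e-08 and 1.3e-07), with 3 and 4 members called lower. The Sertoli cell list had a median of 0.38 on the log2 scale in the same libraries.

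DNA damage signalling and sex body genes had 6 lower, no higher and 15 uncalled members of 21, with 8 lower when adjusted over the list alone. Brca1 was 1.36-fold lower (adjusted p = 0.014), Rad17 1.20-fold lower and the checkpoint kinase gene Atr 1.58-fold lower, Atr with 496 CPM in Brg1 WT replicate 1 and 271.3 to 349 CPM in the other Brg1 WT libraries. The differences of Brca1 and Rad17 turned positive, to 0.053 and 0.23 on the log2 scale, when the median of the undifferentiated spermatogonia list was taken as no change. The camera test gave the list an adjusted p = 0.0025, and an adjusted p = 0.547 with an estimated correlation. Without Brg1 WT replicates 1 and 2 the median moved from -0.27 to -0.093 (camera adjusted p = 0.036) and edgeR called no member, with 5 lower at an unadjusted p under 0.05. Over all 8 libraries the Sertoli cell list had a median of 0.38.

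Transcripts of the piRNA pathway, which silences transposons in germ cells, had 9 lower, no higher and 18 uncalled members of 27, with 15 lower when adjusted over the list alone. Piwil4 fell from 15.5 ± 2.50 to 8.07 ± 1.22 CPM, Tdrkh from 53.3 ± 8.31 to 32.8 ± 3.38 CPM, and Tdrd7 was 1.27-fold lower, a direction that turned to 0.15 relative to the undifferentiated spermatogonia median. The list median was -0.35 (camera adjusted p = 4.0e-06, and adjusted p = 0.464 with an estimated correlation). A single member was called without Brg1 WT replicates 1 and 2, at a list median of -0.23 (camera adjusted p = 9.4e-04). Over all 8 libraries the Sertoli cell list had a median of 0.38 and the pan-germ cell list, which shares 10 of the 27 piRNA genes, one of -0.24. The other 17 had a median of -0.38.

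Pachytene and spermatid genes, which mark later stages, had 8 lower, no higher and 15 uncalled members of 23, and again 8 lower when adjusted over the list alone. Ybx2 fell from 46.6 ± 14.3 to 16.7 ± 1.11 CPM, the chaperone gene Clgn from 16.7 ± 6.88 to 4.57 ± 0.83 CPM, and Ccna1, the germ line cyclin A, from 1.19 ± 0.51 to 0.26 ± 0.076 CPM (SD, n = 4 each). Mean log2 CPM of this list was 2.29, 2.18, 1.66 and 1.55 in Brg1 WT replicates 1 to 4 and 1.17 to 1.42 in the Brg1 cKO libraries. The list had a camera adjusted p = 0.0084, an adjusted p = 0.535 with an estimated correlation, and an adjusted p = 0.115 by camera without Brg1 WT replicates 1 and 2, where 2 members were called lower. The median of the Sertoli cell list was 0.38 over all 8 libraries.

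**Figure D2:**
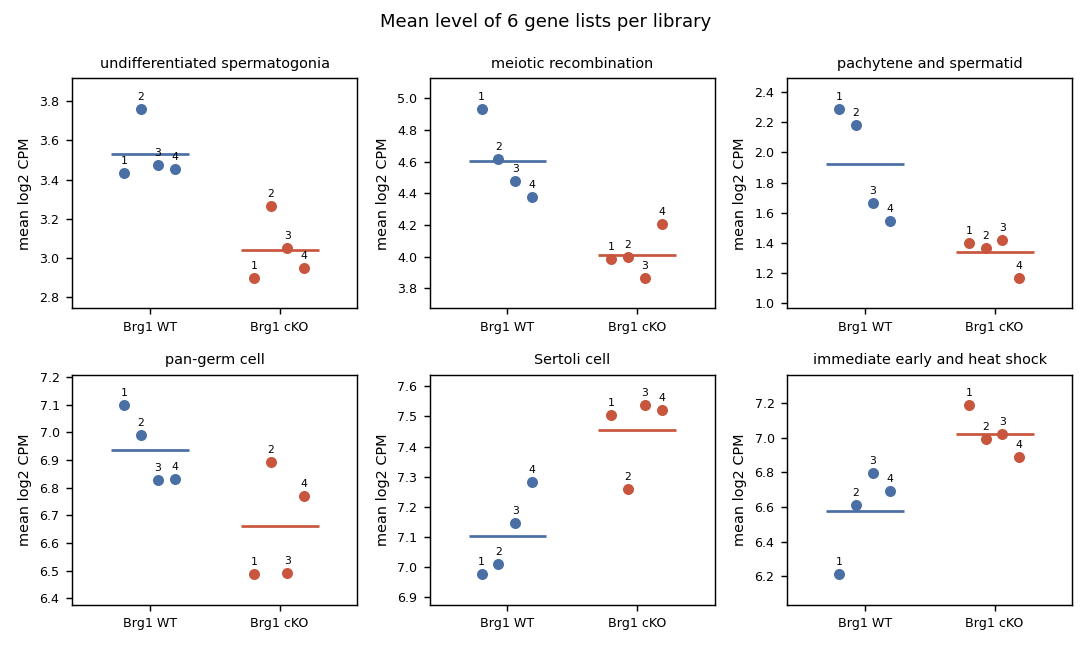
Mean log2 CPM of the members of 6 gene lists (vertical axes) in each library (points, numbered by replicate), with group means as lines. In the pachytene and spermatid panel Brg1 WT replicates 1 and 2, at 2.29 and 2.18, lie above Brg1 WT replicates 3 and 4, at 1.66 and 1.55, and the Sertoli cell panel runs higher in Brg1 cKO.

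Among X- and Y-linked germ cell genes 3 of 19 tested members rose, 2 fell and 14 were not called, with 4 higher and 3 lower when adjusted over the list alone. Tex11 and Tex16, both X-linked, were 1.45-fold and 1.83-fold lower, while the Y-linked helicase gene Ddx3y went from 84.6 ± 14.2 to 124 ± 14.2 CPM (adjusted p = 0.016) with overlap between libraries. The list as a whole did not differ from other genes (camera adjusted p = 0.837), and 1 member, lower, was called without Brg1 WT replicates 1 and 2.

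Of 28 tested Sertoli cell markers 13 rose, 1 fell and 14 were not called, with 17 higher and 1 lower when adjusted over the list alone. Gdnf, the growth factor by which Sertoli cells maintain spermatogonial stem cells, rose from 8.22 ± 1.60 to 18.3 ± 1.20 CPM (SD, n = 4 each; log2 fold change 1.15 ± 0.14 SE, adjusted p = 0.0022). Cst12 was 1.37-fold and Dhh, a hedgehog ligand, 1.44-fold higher. The list median was 0.38 (camera adjusted p = 1.5e-06, and adjusted p = 0.418 with an estimated correlation), and without Brg1 WT replicates 1 and 2 it was 0.23 (camera adjusted p = 7.9e-05), with 2 members called higher.

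Leydig cell genes had 4 higher, no lower and 10 uncalled members of 14, and likewise 4 higher when adjusted over the list alone. Mean log2 CPM of the list was 3.25 to 3.53 in Brg1 cKO replicates 1 to 3 but 2.30 in replicate 4, below the 2.31 to 2.88 of Brg1 WT. Nr5a1, a nuclear receptor of steroid-producing and Sertoli cells, was 1.30-fold higher, Fabp3 1.61-fold higher, and Akr1c14 1.82-fold higher with overlap between libraries. In peritubular myoid and stromal genes 2 of 18 rose, 1 fell and 15 were not called, with 1 higher and 1 lower when adjusted over the list alone. Their mean log2 CPM was 6.48 to 6.61 in Brg1 cKO replicates 1 to 3 but 5.655 in replicate 4, within the 5.59 to 6.28 of Brg1 WT. Pdgfra rose from 115 ± 25.6 to 235 ± 52.5 CPM and Mgp was 1.52-fold higher, while Actg2, a smooth muscle actin, fell from 16.9 ± 2.74 to 7.69 ± 1.70 CPM. List medians were 0.59 and 0.43, with camera adjusted p = 0.011 and 0.013, and adjusted p = 0.418 and 0.688 with an estimated correlation. Without Brg1 WT replicates 1 and 2 the medians were 0.92 and 0.40, and both lists still passed camera (adjusted p = 0.013 and 0.036). In that fit edgeR called no Leydig gene, with 4 higher at an unadjusted p under 0.05, and 1 stromal gene was lower. The stromal list was not called without Brg1 WT replicate 1 (adjusted p = 0.081) or without Brg1 cKO replicate 2 (adjusted p = 0.067).

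No endothelial, macrophage or erythroid gene was called by edgeR, and none had an unadjusted p under 0.05. The list medians were 0.39 over 12 endothelial, 0.48 over 16 macrophage and 0.74 over 6 erythroid genes, with camera adjusted p = 0.098, 0.098 and 0.676. Pecam1 had 148 ± 32.9 CPM in Brg1 WT and 149 ± 60.4 in Brg1 cKO, Mrc1 had 24.8 ± 2.33 and 24.2 ± 3.22, and the globin gene Hbb-bs had 8.97 ± 3.86 and 16.2 ± 15.8 (SD, n = 4 each). These genes were named as the most abundant of their lists and do not stand for them. The log2 fold changes of Pecam1 (0.020) and Mrc1 (-0.035) lay below their list medians, and that of Hbb-bs (0.86) lay above. The endothelial list passed camera without Brg1 WT replicate 2, Brg1 cKO replicate 3 or Brg1 cKO replicate 4 (adjusted p = 0.039, 0.044 and 0.0023), and the macrophage list without Brg1 WT replicate 3 or Brg1 cKO replicate 4 (adjusted p = 0.0073 and 0.0077). With an estimated correlation, over all 8 libraries, each of these lists had an adjusted p = 0.688.

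**Figure D3:**
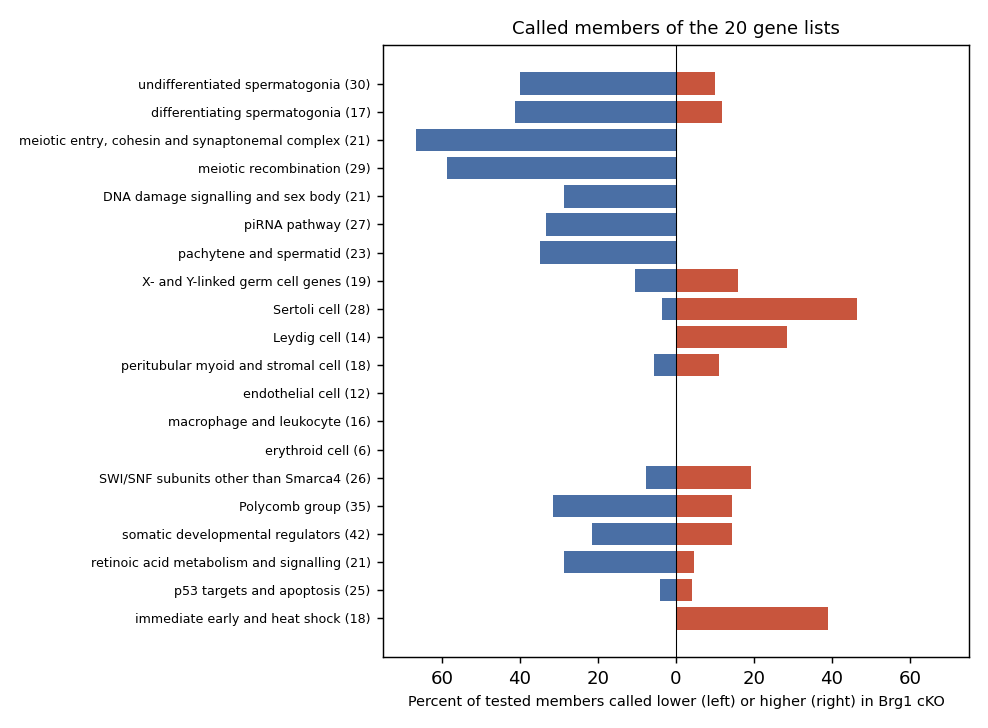
Percent of the tested members of each of the 20 gene lists (number tested in parentheses) called lower (bars to the left) or higher (bars to the right) in Brg1 cKO. Meiotic lists extend only to the left, with 14 of 21 and 17 of 29 members lower, and the Sertoli cell list extends mainly to the right, with 13 of 28 members higher.

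Of 26 tested genes for other subunits of SWI/SNF 5 rose, 2 fell and 19 were not called, with 7 higher and 4 lower when adjusted over the list alone, and camera gave an adjusted p = 0.391 for a shared direction against other genes. Fry gave a mixed adjusted p = 7.7e-05 for change in either direction. That is not particular to this list, since 20.6% of all tested genes were called and most lists passed the same test. The p53 and the X- and Y-linked lists, for example, had a mixed adjusted p = 0.0065 and 1.4e-04. With Brg1 WT replicates 1 and 2 left out edgeR called no SWI/SNF gene, with 6 higher and 3 lower at an unadjusted p under 0.05. Arid1a rose from 289 ± 16.4 to 357 ± 16.9 CPM, a change of 0.30 on the log2 scale that became -0.078 relative to the Sertoli cell median, and Gltscr1l, now Bicral, was 1.30-fold higher. Brd7 fell from 124 ± 1.54 to 107 ± 3.13 CPM, a change of -0.22 that became 0.020 relative to the pan-germ cell median and 0.28 relative to the undifferentiated spermatogonia median.

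Polycomb group genes, which encode repressors of developmental genes, moved both ways, with 11 lower, 5 higher and 19 uncalled of 35, and 12 lower and 5 higher when adjusted over the list alone. Phc1 fell from 114 ± 2.88 to 83.1 ± 5.67 CPM (adjusted p = 0.0027), with 0.049 on the log2 scale relative to the undifferentiated spermatogonia median, and Cbx2 fell from 64.1 ± 1.60 to 39.8 ± 5.71 CPM. Aebp2 rose from 91.1 ± 2.59 to 120 ± 6.28 CPM. Camera gave an adjusted p = 0.262 for a shared direction. Fry gave a mixed adjusted p = 1.8e-05 for change in either direction, a test that most lists passed. Without Brg1 WT replicates 1 and 2, 2 members were lower and 1 higher.

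Somatic developmental regulators, transcription factors of other lineages, had 9 lower, 6 higher and 27 uncalled of 42 tested, with 12 lower and 7 higher when adjusted over the list alone. The homeobox genes Lhx2 and Hoxa3 fell from 6.85 ± 0.82 to 1.83 ± 0.30 CPM and from 1.02 ± 0.15 to 0.22 ± 0.077 CPM (SD, n = 4 each). These changes were 3.74-fold and 4.67-fold, with adjusted p = 5.8e-04 and 0.0031. The list did not pass as a whole (camera adjusted p = 0.317), although it did so without Brg1 WT replicates 1 and 2, at an adjusted p = 0.036 with 6 members lower.

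In the retinoic acid list 6 of 21 members fell, 1 rose and 14 were not called, with 6 lower and 1 higher when adjusted over the list alone. Rbp4, a retinol carrier, fell from 15.1 ± 0.81 to 5.44 ± 0.49 CPM (log2 fold change -1.47 ± 0.11 SE, adjusted p = 2.0e-04), Aldh1a2, a retinoic acid synthesis enzyme, from 71.0 ± 12.6 to 24.98 ± 7.63 CPM, and the receptor gene Rarg from 26.5 ± 0.75 to 15.8 ± 1.92 CPM. The median of this list was 0.019 and its mean -0.25, so that they differed in sign. Camera gave the list an adjusted p = 0.183 against other genes, which passed with statistics from DESeq2 (adjusted p = 0.029) and the edgeR exact test (adjusted p = 0.046) and was an adjusted p = 0.418 with an estimated correlation. Fry, which makes no comparison with other genes, gave an adjusted p = 6.7e-04 for a lower direction. Leaving out Brg1 WT replicates 1 and 2 left 2 members called lower and none higher, with 7 and 2 at an unadjusted p under 0.05.

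For p53 targets and apoptosis genes 1 of 25 rose, 1 fell and 23 were not called, with 1 lower and none higher when adjusted over the list alone (camera adjusted p = 0.545). Aen fell from 66.5 ± 4.02 to 50.2 ± 5.13 CPM. No member was called by edgeR without Brg1 WT replicates 1 and 2, with 2 higher and 2 lower at an unadjusted p under 0.05. The change of Aen turned to 0.093 on the log2 scale relative to the undifferentiated spermatogonia median.

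Immediate early and heat shock genes, which are induced by stimulation or handling of cells, had 7 higher, no lower and 11 uncalled members of 18, with 9 higher when adjusted over the list alone. Fos rose from 691 ± 145 to 1077 ± 118 CPM, Ier2 from 145 ± 28.6 to 221 ± 23.9 CPM and Hspb1 from 95.2 ± 18.7 to 153 ± 25.9 CPM (SD, n = 4 each). The list median was 0.49 (camera adjusted p = 6.4e-05, and adjusted p = 0.418 with an estimated correlation), beside 0.38 for the Sertoli cell list. The median was 0.28 without Brg1 WT replicates 1 and 2 and the list still passed camera (adjusted p = 1.7e-04), while edgeR called no member, with 8 higher at an unadjusted p under 0.05.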

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

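The tests of GC content and length, of the differences between lists, of the immediate early genes and of undifferentiated spermatogonia markers against the steepest falls were chosen after the results were seen, while the splits of the libraries and the test of the steepest falls without Brg1 WT replicates 1 and 2 were set down before their outcome was seen. The choice to judge differences between lists by adjusted rather than unadjusted p was also made after both had been seen. The 3312 genes called between the genotypes were compared with the other ways of dividing the 8 libraries into 4 and 4. Of the 35 splits, 1, the real one, gave as many genes, and the highest of the others gave 17. This argues against chance division of the libraries as the source of the count, although 1 in 35 is the smallest share the comparison can give.

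In 198 groups of 4 values (library measures, list levels and CPM of named genes, by genotype), 10 held a library whose gap to the nearest of the others took most of the group's range. Chance alone gives about 1 in 20, so that 10 is about the number chance gives. The libraries named below are therefore not shown to be outliers. The undifferentiated spermatogonia list had a mean log2 CPM of 3.76 in Brg1 WT replicate 2, against 3.43 to 3.48 in the rest of its group. Meiotic entry, cohesin and synaptonemal complex genes stood at 6.48 in Brg1 WT replicate 1, against 6.02 to 6.07. Sertoli cell markers were at 7.26 in Brg1 cKO replicate 2, below the 7.50 to 7.54 of the other Brg1 cKO libraries, and Nr5a1 in that library had 121.1 CPM against 145.5 to 148.1. Peritubular myoid and stromal genes had 5.66 in Brg1 cKO replicate 4, against 6.48 to 6.61. Msh5 had 35.97 CPM in Brg1 WT replicate 1 against 24.1 to 26.1, and Arid1a 265.1 CPM in the same library against 295.2 to 299.7. Piwil4 had 6.26 CPM in Brg1 cKO replicate 3 against 8.56 to 8.86. Ddx3y had 105.7 CPM in Brg1 WT replicate 4 against 75.1 to 79.9, and Ier2 had 256.4 CPM in Brg1 cKO replicate 1 against 207.3 to 211.5.

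Germ cell lists had lower medians and the Sertoli cell list a higher one in Brg1 cKO, and GC content and length trends were argued against as the whole cause, since all 8 of these lists stayed past camera's threshold in the same direction once the trends were taken out, although with an estimated correlation none passed before that step either (adjusted p = 0.418 to 0.547). A lower share of germ cells may account for the rise of somatic markers, but the test had little reach: the lists of 4 other somatic types set against the Sertoli list gave a smallest adjusted exact permutation p = 0.971 while varying between libraries by SDs of up to 0.75, more than the 0.35 by which the Sertoli list rose, so that this cannot be told apart from a change within Sertoli cells. Whether such a share could account for the whole fall of the meiotic lists also stays open. Meiotic recombination genes were 0.31 lower relative to a list of pan-germ cell genes, beyond SDs of 0.17 and 0.12 (exact permutation p = 0.0286, the smallest that 4 against 4 can give), but this was the largest of 4 such contrasts against a list chosen after its values were seen, and the adjusted p = 0.143 over 10 contrasts decides nothing, since that minimum could hardly pass after adjustment. The genotype itself and a difference in meiotic stage remain open as well.

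The 62 genes at least 4-fold lower in Brg1 cKO, with a median log2 fold change of -2.41, were weighed against a loss of undifferentiated spermatogonia. An even loss of that population is argued against as the whole cause, because its markers would then fall about as far. The median of the 30 tested was -0.50, with an SD of 0.71 between members, and 1 of them was at least 4-fold lower. The largest falls among them were those of Upp1 (-2.08), itself 1 of the 62, Eomes (-1.79) and Nanos3 (-1.78). The 3 called higher were Nanos2 (0.94), Bcl6b (0.63) and Itga6 (0.44). Members also made by other cell types, such as Itga6, could hide a loss. Whether that holds for Nanos2 and Bcl6b was not tested. The list's values were known before this comparison, and the 62 genes were picked for their fall. The comparison replaced a test set down earlier, in which all 62 stayed called with that median taken as no change. The earlier test decides nothing, because genes picked for a 4-fold fall could hardly lose their call by that shift. The higher pachytene and spermatid transcripts of Brg1 WT replicates 1 and 2, whether from a later stage or a higher share of germ cells, were argued against as the whole cause, because the median of these genes was -2.26 without those libraries, with 35 of the 62 still called. The genotype stays open, as does a loss of some subset of cells that these markers do not follow, which was not tested.

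Immediate early and heat shock genes had a median log2 fold change of 0.49. A higher share of somatic cells may account for this, since the list rose by 0.094 more than the Sertoli cell list, less than the SDs between libraries of 0.17 and 0.19 (exact permutation p = 0.486, adjusted p = 0.810 over the 10 contrasts). With 4 libraries of each genotype and these SDs, the contrast does not exclude a rise of the list beyond that of the Sertoli cell list. A difference in the handling of cells was not tested and stays open, as does the genotype.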

How the results depend on the processing

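The fits without Brg1 WT replicates 1 and 2, without abundant transcripts, with GC and length offsets and with a list median as reference were chosen after seeing the data. Smarca4 stayed lower and called in every alternative, from -1.02 to -1.90. Counts of called genes stayed within 1.5 times the main values with limma-voom, the edgeR exact test, RLE, upper-quartile factors, both filters, abundant transcripts left out and GC and length offsets (2846 to 3482). DESeq2 called 4445 genes, 2238 higher (50.3% of its calls) and 2207 lower, and the cause of the higher number was not tested. It was run on all 28460 genes and gave 11678 no adjusted p, among them the 5463 with no count. The others were not divided by cause. A test for changes over 1.5-fold called 125 genes, 4 higher and 121 lower, by its stricter construction. Low depth limits genes near 1 CPM, such as Ccna1 and Hoxa3.

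Leaving out 1 library gave 1608 to 3477 genes, 556 to 1497 higher and 1052 to 1980 lower, lowest without Brg1 cKO replicate 1. Without Brg1 WT replicates 1 and 2, 438 genes were called, 96 higher and 342 lower, and 425 of them were among the 3312. All 3312 genes kept their direction, which shows little. Of these, 3007 had no overlap between the genotypes and could hardly turn when libraries were left out. In that fit 28 of the 65 named genes other than Smarca4 were no longer called, and the 1.5-fold test no longer called 43 of the 65. Leaving out another pair of Brg1 WT libraries gave 244, 270, 586 and 658 genes where the pair held replicate 1 or 2, and 2167 without replicates 3 and 4; the cause was not tested. Directions that turned in that fit were those of Pecam1 (-0.16), Mrc1 (0.083), the X- and Y-linked list (0.11) and, by camera, the macrophage list (median 0.11). List directions here are camera's; the retinoic acid list stayed lower by camera while its median went from 0.019 to -0.11. Without single libraries they turned for Pecam1 (-0.12 without Brg1 WT replicate 1, -0.29 without Brg1 cKO replicate 2, range -0.29 to 0.17), Mrc1 (0.021 without Brg1 WT replicate 1, 0.042 without Brg1 cKO replicate 4, range -0.087 to 0.042), Hbb-bs and the erythroid list (-0.032 each without Brg1 cKO replicate 2, highest 1.19 and 1.06) and the X- and Y-linked list (0.037 without Brg1 WT replicate 1, 0.044 without Brg1 cKO replicate 1). Pecam1 was -0.028 with limma-voom, and the somatic developmental regulators' median was 0.24 with the stricter filter; the causes were not tested.

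The reference level set the balance of calls by its own construction, shifting all genes by the list median. With the pan-germ cell median (-0.24) as no change, 6929 genes were called, 6101 higher and 828 lower, and Mrc1 (0.21) and Brd7 (0.020) turned. With the undifferentiated spermatogonia median (-0.50) there were 11050, 10643 higher and 407 lower, and Brca1 (0.053), Rad17 (0.23), Tdrd7 (0.15), Mrc1 (0.46), Brd7 (0.28), Phc1 (0.049) and Aen (0.093) turned. With the Sertoli cell median (0.38) there were 8569, 72 higher and 8497 lower against 1412 and 1900 in the reported fit, and Pecam1 (-0.36) and Arid1a (-0.078) turned.

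With the replicate number as a block 1914 genes were called, 745 higher and 1169 lower, 11 of the 65 were not called, and Pecam1 was -0.030. Camera passed 1 list in that fit that it had not called in the main fit. Deviations of same-numbered libraries correlated across genes at -0.21, 0.13, -0.37 and 0.15, and only Brg1 WT replicate 4 correlated best with its own number. These values gave no sign that the numbers pair the libraries, but they are too few to exclude it.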

Other observations

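The gene groups described here were written after the 20 fixed lists, and the pan-germ cell, developmental transcription factor and synapse lists after values had been seen, as was the choice of genes named and the test of Gdnf. Of 36 genes of DNA replication and the mitotic cycle 15 fell in Brg1 cKO, none rose and 21 were not called. Top2a, a topoisomerase of dividing cells, fell from 430 ± 47.8 to 297 ± 23.8 CPM (SD, n = 4 each), and Rrm2, a subunit of ribonucleotide reductase, was 1.55-fold lower. The list median was -0.36 (camera adjusted p = 4.1e-09, and adjusted p = 0.352 with an estimated correlation), beside -0.24 for the pan-germ cell list and 0.38 for the Sertoli cell list. In Brg1 cKO replicate 2, replication genes (mean log2 CPM 5.62) and pan-germ cell genes (6.89) stood highest of their group and Sertoli cell markers (7.26) lowest. Of 20 cholesterol synthesis genes 6 fell, among them Lss and Sqle at 1.37-fold and 1.35-fold lower, and 1, Ebp, rose, at a list median of -0.26 (camera adjusted p = 4.5e-04, and adjusted p = 0.345 with an estimated correlation). Of 20 pan-germ cell genes 3 fell, Tex14, Tuba3a and Rnf17, none rose and 17 were not called, at a median of -0.24 (camera adjusted p = 8.0e-04, and adjusted p = 0.483 with an estimated correlation).

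Transcription factors of developmental families had 40 lower, 14 higher and 83 uncalled members of 137, at a median of -0.18 (camera adjusted p = 0.0024, and adjusted p = 0.352 with an estimated correlation). Ebf3 fell from 21.5 ± 2.70 to 4.50 ± 1.17 CPM, Nr2e1 from 3.21 ± 0.44 to 0.25 ± 0.12 CPM and Dlx1 from 8.75 ± 1.04 to 2.38 ± 0.12 CPM (SD, n = 4 each), while Sox8, which Sertoli cells also express, was 1.39-fold higher. These families, chosen after such falls had been seen, gave 13 of the 62 genes at least 4-fold lower. Synapse and neuronal adhesion genes had 9 lower, no higher and 22 uncalled members of 31, with Ctnnd2 2.92-fold, Cbln2 4.63-fold and Nrxn2 2.16-fold lower (camera adjusted p = 0.0038, and adjusted p = 0.345 with an estimated correlation). In the same libraries the Sertoli cell list had a median of 0.38 and the pan-germ cell list one of -0.24. The developmental family and synapse lists were not tested by camera without Brg1 WT replicates 1 and 2.

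Of 9 tested Wnt ligand genes 3 fell, Wnt3, Wnt7b and Wnt9a, and 1 rose, Wnt5a, from 30.3 ± 4.90 to 51.9 ± 5.49 CPM (camera adjusted p = 0.462 for the list). Cytosolic ribosomal protein genes had 8 higher, no lower and 69 uncalled members of 77, at a median of 0.091 (camera adjusted p = 0.0017, and adjusted p = 0.618 with an estimated correlation), with the X-linked Rps4x 1.74-fold higher. Close paralogs and pseudogenes make ribosomal protein values uncertain. The 727 tested genes of the X chromosome had 98 higher, 56 lower and 573 uncalled, at a median of 0.10 (camera adjusted p = 0.025, and adjusted p = 0.345 with an estimated correlation). No mitochondrially encoded transcript was called among 13, and none had an unadjusted p under 0.05.

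A hypothesis is that Gdnf may rise beyond the share of Sertoli cells. Gdnf rose by 0.84 more than the other 27 Sertoli markers, beyond SDs of 0.14 and 0.31 (exact permutation p = 0.0286, the smallest that 4 against 4 can give). The adjusted p = 0.143 over the 10 contrasts run decides nothing, since that minimum could hardly pass after adjustment, and the question stays open because Gdnf was picked from the list for its small p. In the edgeR fit with the Sertoli cell median taken as no change, Gdnf was 0.78 higher (adjusted p = 0.0013). That fit treats the median as known without error. Over the tests of all alternatives the adjusted p of Gdnf ran from 2.2e-12 to 0.042. That range does not bear on the question, since no other alternative took the Sertoli cell level into account.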
